A study of Daphnia magna with 4 samples.

How the data were processed

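RNA was sequenced from 4 libraries of whole Daphnia magna, a freshwater crustacean used in toxicity testing. Each library pooled 3 animals. The design text of the series speaks of 5 such samples, and 4 libraries were listed and analysed here. How the 5 relate to these 4, in total or per group, is not given in the sources used here. Per the labels, 2 libraries came from animals aged 7 days that had been exposed for 96 hours to 40 µM atrazine, a triazine herbicide, carried in the solvent DMSO. The other 2 came from animals of the same age with no exposure, and the labels do not say whether these received the carrier solvent. The label of atrazine replicate 4 spells the compound with a different first letter, and its title places it with the atrazine libraries. Libraries keep the replicate numbers of their titles (2 and 4 for atrazine, 1 and 5 for untreated). The labels describe each library as its own pool of animals, and no batch or sequencing date is given.

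The submitters' processing notes name FastQC, Trimmomatic, GSNAP, Subread, featureCounts and edgeR, without versions or settings. The genome build, the annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Per the labels' protocols, libraries were made with the TruSeq RNA kit, version 2. One deposited table holds raw read counts for 26646 features, of which 5285 had no count in any library. The other deposited table holds values for 14528 of these features. Each of its columns sums to 1000000, and each value is the raw count times one factor per library, so these values are CPM (counts per 1000000 reads) over the features the authors kept, with no composition factor. Dividing by that factor gave whole reads, equal to the raw counts within a tolerance of 1e-06, for 100% of the values. All columns were matched to a library by its title, and 0 columns were left unmatched.

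Features are named only by the letters rna and a number. None of the IDs (0) matched an identifier or accession in the RefSeq gene table available here, and the files do not pair the IDs with gene names. The 30 gene lists fixed before the data were examined (detoxification enzymes, stress proteins, globins, yolk, cuticle, moult, digestion, energy metabolism and tissue markers) therefore could not be made, and 0 list tests were run. The rule for naming features, fixed at the same time, gave for this case the 2 IDs with the largest rise and the 2 with the largest fall among features past the threshold, with a mean log2 CPM of at least 1 and both atrazine libraries on the same side of both untreated libraries. No chromosome position is given, since no annotation of the numbering was used here.

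Raw counts were tested with edgeR 4.0.16 in R 4.3.3. Features were kept by filterByExpr (minimum count 10), which left 15196. Libraries were scaled by TMM factors, and the quasi-likelihood F test compared the 2 groups with no covariate. The groups share no replicate number, so no block was fitted. Adjusted p is by Benjamini-Hochberg over all tested features, two-sided, with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F, and 95% intervals use a t quantile of 2.48, from 2 residual and 3.7 prior degrees of freedom. CPM values are TMM-scaled, and log2 CPM values carry a prior count of 2. The common dispersion of 0.0196 corresponds to a coefficient of variation of 14% between libraries of a group.

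The test was checked on simulated data: 5 simulations of the comparison of atrazine with untreated libraries, each with 15196 features drawn from the real means, library sizes and dispersions and 200 features changed. The changed features were drawn from those with a mean log2 CPM of at least 1, and both groups were given the same dispersion. The test called 100% of the 4-fold changes, 72.8% of the 2-fold changes and 11.6% of the 1.5-fold changes. Of all calls in these simulations, 14.6% were of unchanged features, more than the 5% that the threshold aims at. These rates do not cover changes of lower features, or the unequal spread of the real groups. The share of false calls also depends on the number of changed features, which was set at 200.

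Library totals ran from 16044118 to 17675476 reads. With 2 libraries per group, the median 95% interval of a feature with a log2 CPM of at least 1 reached 0.35 to either side of its log2 fold change. Wilson intervals of read shares are at 95% and cover counting error only, since reads carry no molecular identifiers.

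The alternatives were RLE, upper-quartile and library-size scaling, DESeq2 1.42.0, limma-voom (limma 3.58.1), the edgeR exact test, the legacy quasi-likelihood method with robust shrinkage, no filter, a filter of 1 CPM in 2 libraries, limma on log2 of the deposited CPM plus 1, and each library left out in turn. The test on the features the authors kept, as reads recovered from the deposited CPM, was added after seeing the data.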

Results

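The data are read counts of 4 RNA libraries from whole Daphnia magna, 2 from animals kept for 96 hours in 40 µM of the herbicide atrazine and 2 from unexposed animals, with 3 animals in each library. The totals were 16044118 and 16468195 reads for atrazine replicates 2 and 4, and 16538025 and 17675476 reads for untreated replicates 1 and 5. Between 19404 and 19541 features had at least 1 read in a library. The 10 most abundant features took 17.4% and 17.8% of the reads in the atrazine libraries, and 19.7% and 22.5% in untreated replicates 1 and 5.

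The libraries separated by treatment along the first principal component of log2 CPM, which held 73.5% of the variance over the 12961 features with a mean log2 CPM of at least 1. The atrazine libraries lay together at scores of 27 and 27.8. Untreated replicate 1 lay at -15.7 and untreated replicate 5 at -39.1. Across features, which are not independent replicates, Pearson's r was 0.992 between the atrazine libraries and 0.983 between the untreated ones. It was 0.976 and 0.977 between untreated replicate 1 and the atrazine libraries, and 0.963 and 0.964 between untreated replicate 5 and the atrazine libraries. The log2 difference between libraries had an SD of 0.245 in the atrazine pair and 0.394 in the untreated pair. More than 2-fold differences were found for 66 features in the atrazine pair and 314 in the untreated pair. Each library was counted as its own sample, as the labels describe it. Neither pair agreed within sampling noise, as one library deposited under different names would, with a chi-square per degree of freedom of 15.2 for the atrazine pair and 111 for the untreated pair.

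The main comparison asked which transcripts changed in abundance in animals exposed to atrazine. The exposed animals also received the carrier DMSO, and the labels do not say whether the untreated ones did. If they did not, effects of the carrier and of atrazine cannot be told apart here. Of 15196 tested features, 186 were higher and 132 were lower in exposed animals (edgeR quasi-likelihood test, adjusted p below 0.05, n = 2 libraries per group), together 2.09% of those tested. Rises were mostly moderate: the median rise was 1.23 on the log2 scale, or 2.35-fold, with quartiles of 0.94 and 1.77. Falls were larger, with a median log2 fold change of -1.96, or 3.89-fold lower, and quartiles of -2.64 and -1.35. These medians cover features past the threshold only, so they do not show that falls were larger in general. At least 2-fold changes were found for 129 of the features that rose and for all but 9 of those that fell. At least 4-fold changes were found for 30 that rose and 62 that fell. At least 8-fold changes were found for 11 features that rose and 27 that fell. An unadjusted p below 0.05 was found for 2677 features, where 760 would be expected with no effect. In simulated data with the same dispersion in both groups, 14.6% of the calls were of unchanged features. The counts moved by more than 1.5 times when any library but untreated replicate 5 was left out. The lone library of a group then borrows its spread from the other group, so these counts cannot be set against the main ones. The untreated libraries did not contribute equally. As described below, replicate 5 lay further from the atrazine libraries than replicate 1 for most of the changed features. The counts also moved by more than 1.5 times with the method. DESeq2 called 580 higher and 355 lower, the edgeR exact test 813 and 516, and limma on the deposited CPM 287 and 205. The quasi-likelihood test with no filter called 12 and 1, and library-size scaling called 209 lower.

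**Figure D1:**
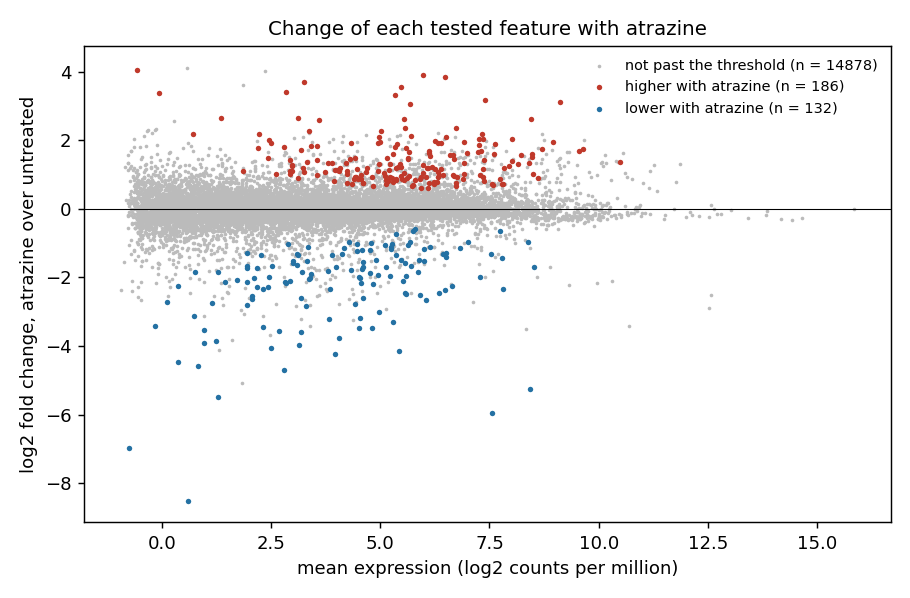
Log2 fold change of atrazine over untreated libraries (vertical axis) against mean expression in log2 CPM (horizontal axis), one point per tested feature, with 2 libraries per group. Red points are the 186 features that were higher with atrazine, blue points the 132 that were lower, and grey points those not past the threshold; the falls reach further from 0 than the rises.

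In unexposed animals both the features that rose and those that fell had a median level above that of all features. The median log2 CPM in the untreated libraries was 4.73 for the 186 that rose, 4.92 for the 132 that fell and 3.97 for all tested features. In the atrazine libraries the medians were 6.04, 2.74 and 3.96. Together, the features that rose took 2.6% ± 0.341 of all reads in the atrazine libraries and 0.966% ± 0.0941 in the untreated ones (SD, n = 2 each). The features that fell took 0.243% ± 0.0304 in the atrazine libraries and 0.832% ± 0.192 in the untreated ones (SD, n = 2 each). These sets were chosen by the same test, so the levels and shares describe them and are not independent evidence of their direction. Choosing features as lower with atrazine also favours a high untreated level. Calls varied with abundance: 0.1% of features at a log2 CPM of 0 to 2 were called higher, and 3% at 6 to 8. For lower calls these were 0.69% and 0.93%. The level comparison is therefore no evidence of a trait of the changed genes.

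The named rises and falls follow the rule fixed in advance, and the files give no gene names for them. Feature rna13152 rose 15-fold, from 7.93 ± 4.4 CPM in untreated animals to 119 ± 18.8 CPM with atrazine (SD, n = 2 each). Its log2 fold change was 3.91, with an SE of 0.4 and an edgeR adjusted p of 0.024. Feature rna18800 rose 14.3-fold, from 11.7 ± 0.479 to 168 ± 13.2 CPM, and had the smallest p of all tested features, with a log2 fold change of 3.84, an SE of 0.12 and an edgeR adjusted p of 0.0017. Its raw counts were 201 in both untreated libraries, and 2797 and 2624 in the atrazine libraries. Feature rna5416 fell by 5.94 on the log2 scale (SE 0.8, edgeR adjusted p of 0.034), from 370 ± 293 CPM in untreated animals to 6.03 ± 3.66 CPM with atrazine. Its untreated level differed between the libraries, at 163 CPM in replicate 1 and 577.7 CPM in replicate 5. Feature rna869 fell by 5.48 on the log2 scale (SE 0.7, edgeR adjusted p of 0.03), from 4.46 ± 2.66 to 0.0935 ± 0.0469 CPM. It had 43 and 112 reads in the untreated libraries and 2 and 1 in the atrazine libraries, so the ratio of 48.7 between groups has a 95% counting interval of 16.4 to 238.9. Of these 4 features, rna18800 stayed past the threshold in all 15 alternatives, rna13152 in 12, and rna5416 and rna869 in 11 each. The size of these changes moved when single libraries were left out, least for rna18800. All values from such fits stayed within the 95% intervals of the main fit. These were 2.92 to 4.9 for rna13152, -7.92 to -3.97 for rna5416 and -7.22 to -3.75 for rna869. Without untreated replicate 1 the log2 fold change was 4.63 for rna13152 and -6.59 for rna5416, and without untreated replicate 5 it was -4.77 for rna5416 and -4.69 for rna869. For rna869, limma on log2 of the deposited CPM plus 1, which understates changes of low features, gave -2.24. Without atrazine replicate 2 the edgeR adjusted p was 0.083 for rna13152, 0.12 for rna5416 and 0.14 for rna869, with log2 fold changes of 3.73, -6.76 and -6.06. Without atrazine replicate 4 it was 0.078 for rna5416 and 0.084 for rna869, with log2 fold changes of -5.42 and -5.06.

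No feature that rose was at 0 in both untreated libraries. Among the features that fell, 2 had 0 reads in both atrazine libraries. One had 33 and 61 reads in untreated replicates 1 and 5, which is at least 14.7-fold lower with atrazine against a floor of 3 counts per library. The other had 17 and 15 reads, which is at least 5-fold lower. With these 2 features set at their bounds, the median fall stayed at -1.96 on the log2 scale, and 26 in place of 27 features fell at least 8-fold.

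The 2 untreated libraries differed more over the features that fell than over those that rose. Their median absolute log2 difference was 0.43 over the 132 features that fell, 0.23 over the 186 that rose and 0.2 over all tested features. In the atrazine pair the same medians were 0.29, 0.24 and 0.13. Of the features that fell, 107 (81.1%) were higher in untreated replicate 5 than in replicate 1. Of the features that rose, 56 (30.1%) were, against 48.5% of all tested features. Untreated replicate 1 thus lay between the atrazine libraries and untreated replicate 5 for most of the changed features. These differences were not tested, since each pair is a single difference between libraries.

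**Figure D2:**
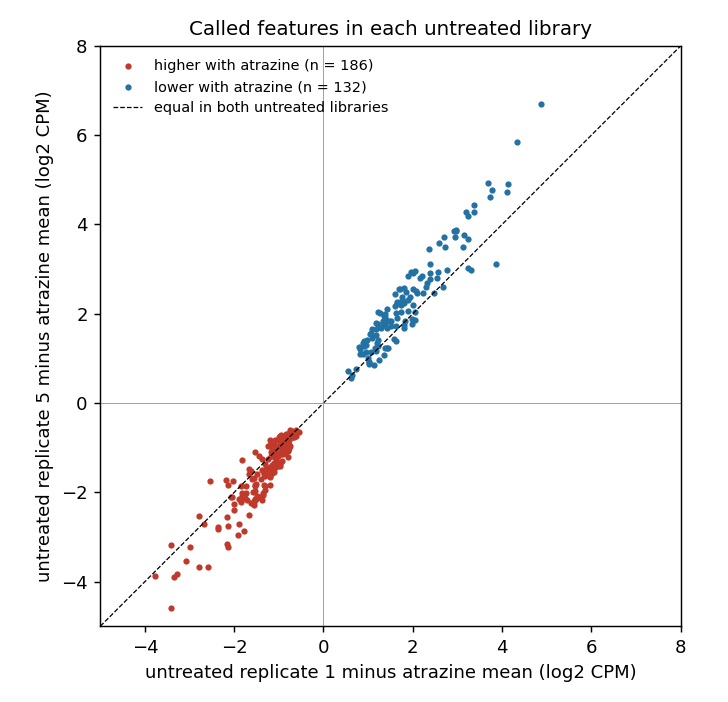
Level of each called feature in untreated replicate 1 (horizontal axis) and untreated replicate 5 (vertical axis), as log2 CPM minus the mean of the 2 atrazine libraries; red, the 186 features higher with atrazine; blue, the 132 lower with atrazine; dashed line, equal levels. Most blue points (107) lie above the dashed line, and most red points below it.

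The features that fell were not spread evenly over the feature numbers. Between numbers 5178 and 5552, 26 of the 132 lay among 313 tested features in a stretch of 400 numbers, or 8.3%, against 0.71% of the tested features elsewhere. None of the features that rose (0) lay in this stretch. In 10000 random draws of 132 tested features, no stretch of 400 numbers held more than 14, and the permutation p of 1e-04 is the smallest these draws can give. Feature rna5416 lies in this stretch. The other 287 tested features of the stretch had a median log2 fold change of -0.05. The densest stretch of 400 numbers for features that rose held 10 of 186, with a permutation p of 0.5. Over shorter distances the features that rose also lay closer together than random draws: 27 followed another within 10 numbers, against a random mean of 14.8 (permutation p = 0.002), and for those that fell the numbers were 32 and 7.5 (permutation p = 1e-04, the smallest these draws can give). The lengths of 400 and 10 numbers were chosen after seeing the data. The count in the stretch was 0 without atrazine replicate 2, 3 without atrazine replicate 4 and 49 without untreated replicate 1. With all libraries, the count in the stretch was 41 with DESeq2, 41 with the edgeR exact test and 1 with no filter.

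**Figure D3:**
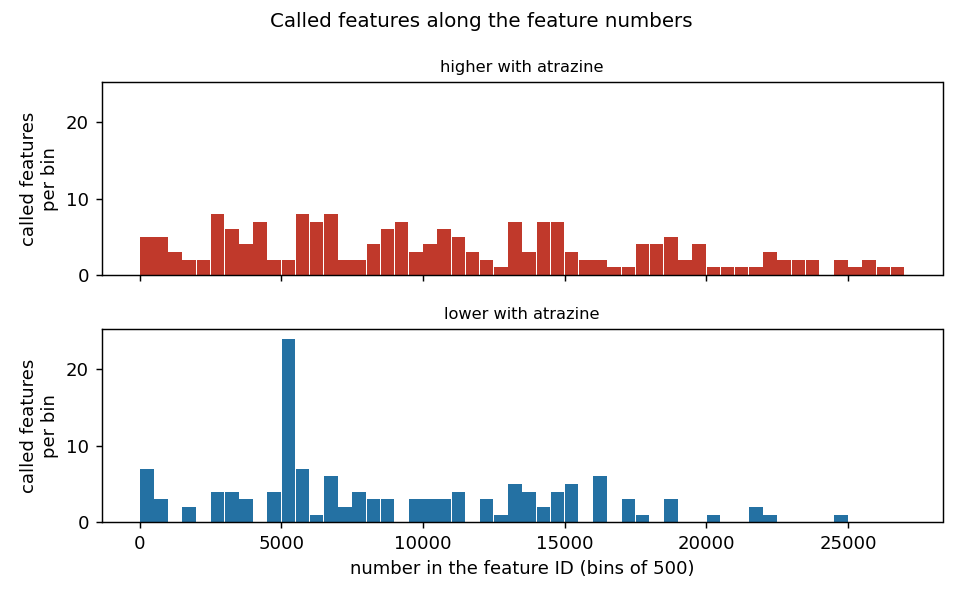
Number of called features (vertical axis) in bins of 500 consecutive feature numbers (horizontal axis), above for features higher with atrazine and below for features lower with atrazine. The bin that starts at 5000 holds 24 features that fell and 2 that rose.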

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

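All 318 called features kept the sign of their change under every alternative in which they were tested. In all 318, both atrazine libraries lay on the same side of both untreated libraries. The kept signs were thus largely fixed in advance and are no support. The number of calls varied widely. Higher and lower calls were 580 and 355 with DESeq2, 813 and 516 with the edgeR exact test, 287 and 205 with limma on the deposited CPM, and 12 and 1 with no filter on low counts; library-size scaling gave 209 lower calls. At least 2-fold changes numbered 635 with DESeq2, 770 with the exact test and 13 with no filter, against 252. The DESeq2 and exact tests called all 318 features again, limma-voom 278 of them and the unfiltered test 13. The cause of these shifts was not tested. With each library left out in turn, 3 to 673 features were higher, 0 to 582 lower and 3 to 878 changed at least 2-fold; the lowest counts came without atrazine replicate 2 and the highest without untreated replicate 1. The lone library of a group is then assumed to vary like the other group. Without an atrazine library the spread is thus that of the untreated pair. Without either untreated library it is that of the closer atrazine pair. The fits without untreated replicate 1 and without replicate 5 share this spread, so it does not by itself explain why their counts differ. The DESeq2 counts moved too with a library left out. In these fits DESeq2 gave no adjusted p for 1211 to 2109 features, against 0 features with all 4 libraries. The size of the shift is therefore not compared between the methods. RLE and upper-quartile scaling, limma-voom, the legacy quasi-likelihood method, the CPM filter and, added after seeing the data, the features the authors kept (187 higher, 131 lower) stayed within 1.5 times of every count. No scaling moved the median log2 fold change of all features beyond -0.043. The list tests and their alternatives were not run, since the IDs carry no gene names. No paired analysis was possible because the groups share no replicate number. At this depth and 2 libraries per group, 1.5-fold changes were mostly not detectable. In simulation 11.6% were called, for features with a mean log2 CPM of at least 1 and the same dispersion in both groups.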

Other observations

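The tests on the number of neighbours, on regrouping the libraries and on the share of mixed RNA (seen first over the called features alone) were chosen only after the result was seen; the other tests of explanations below had their predictions written before their values were computed.

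A set of 7 highly abundant features, found after seeing the data, was at least 4-fold above every other library in untreated replicate 1 alone. They took 5.58% of its reads (Wilson 95% interval 5.56 to 5.59), against 0.5% and 0.419% in atrazine replicates 2 and 4 and 0.259% in untreated replicate 5. The 2 with most reads, rna11285 and rna11286, had 329955 and 326766 reads in untreated replicate 1 and 15142 and 17563 in untreated replicate 5. Their log2 fold changes were -2.88 (SE 1.28) and -2.5 (SE 1.22), with edgeR adjusted p of 0.33 and 0.37. All 7 features were lower in both atrazine libraries than in untreated replicate 1, by a median log2 difference of -3.44, and higher in both than in untreated replicate 5, by a median of 0.86. By the same rule, 0 features stood above the others in atrazine replicate 2, 1 in atrazine replicate 4 and 12 in untreated replicate 5. Untreated replicate 5 also had 26 features at least 4-fold below every other library, against 0 in untreated replicate 1. At 2-fold it stood apart most often of the 4 libraries, with 143 features above and 140 below all others, against 17 and 45 in untreated replicate 1. With 1 pool of animals showing the rise, a direction with atrazine cannot be given for these features.

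The untreated pair differed more than the atrazine pair, with a ratio of 1.61 between the SDs of their log2 differences. The tables argue against library size, since the ratio was 1.61 to 1.62 in 10 draws thinned to the smallest library, and against a few abundant features, since it was 1.51 without the 20 most abundant features and the 7 above. RNA of exposed animals mixed into untreated replicate 1 may have brought it closer to the atrazine libraries. Mixing could not move the 7400 features within 0.2 log2 between atrazine and untreated replicate 5. Among these the ratio was still 1.27 (95% interval 1.22 to 1.31 by bootstrap over features). That of the median absolute deviations was 1.57 (1.51 to 1.64), as over all features (1.57). These intervals cover no variation between pools of animals, since each group has a single pair. For these libraries the values argue against mixing as the whole cause. For features at least 3-fold apart, the implied share of mixed RNA was 0.57 from those lower with atrazine. It was 0.26 from those higher with atrazine, a difference of 0.31. The bound of 0.1 set for this difference proved too narrow. In the atrazine pair, with the groups' roles exchanged, the measure gave 0.1 from the features lower and -0.15 from those higher with atrazine. With roles exchanged, the matching difference is higher minus lower, at -0.25. This is beyond the bound but opposite in sign to 0.31. Mixing as part of the cause stays open for these features. That untreated replicate 5 rather than replicate 1 is the library that departs stays open, as does a difference in the state of the pooled animals, and no biological explanation was tested, since the labels give no factor that divides the untreated libraries.

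Changed features of both directions lay close together in feature number, beyond the stretch of falls described above. Of the 132, 32 followed another within 10 numbers, against a mean of 7.5 and a maximum of 18 in 10000 random draws (permutation p = 1e-04, the smallest these draws can give), which argues against chance placement; outside the stretch 15 did, against a maximum of 14. The 186 that rose showed it too, with 27 against a mean of 14.8 (permutation p = 0.002). If the numbers follow the order of genes along the genome, which no source used here states, a candidate explanation is that neighbouring genes respond together. Reads shared between near-identical neighbours might give the same picture. The ratio of counts changed between libraries, judged against counting noise alone, in 22 of 32 neighbouring pairs that fell. This is 68.8% (exact 95% interval 50 to 83.9), and it does not settle the question. The interval reaches down to the 50% set in advance, and it treats pairs that have a feature in common as independent. Partial sharing needs sequences not analysed here. Across features, the log2 fold changes of immediate neighbours in number had an r of 0.21, falling to 0.05 at a distance of 5. The 7 features raised in untreated replicate 1 alone also lay in runs of adjacent numbers, such as rna11285 and rna11286. Neighbours thus moved together between libraries of the same group too. Closeness in number therefore does not by itself show a joint response to atrazine.

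Regrouping the 4 libraries gave 318 calls in the real grouping and at most 0 in the other 2 (unadjusted p below 0.05 for 208 and 119 features, and 0 calls by DESeq2). Each of the other 2 groupings put 1 atrazine and 1 untreated library in each group. The difference between treatments was then counted as spread within groups, which lowers the number of calls. Their unadjusted counts of 208 and 119 lay below the 760 expected with no effect. The 0 calls there are therefore no measure of chance calls, and no conclusion is drawn from them. The real grouping was also 1 of only 3, too few for a share under 0.05.

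The features the authors kept do not follow from these 4 libraries alone by a rule of more than 1 CPM in 2 libraries. All features that passed this rule were kept, with a second-largest CPM of at most 0.997 among those left out, but 260 kept features did not pass it and 43 were above 1 CPM in none of the 4. The design text of the series speaks of 5 samples, and whether the authors filtered on a further library is not given in the sources used here.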
